A study of Homo sapiens with 8 samples.

How the data were processed

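RNA was measured by sequencing in 8 libraries of LN229-TAZ(4SA) human glioblastoma cells, 2 for each of 4 groups: regular culture at 1 h and 7 h, and culture with AF at 1 µM without glucose at 1 h and 7 h. Per the labels' protocols, libraries were made with a SMART-Seq mRNA HT kit and Nextera XT, which do not mark strand, so the reads of overlapping and antisense genes cannot be told apart. Reads were aligned with HISAT2 to the GRCh38 build and processed with edgeR, per the submitters' processing notes; the versions, the counting tool and the filter on low genes are not given in the sources used here.

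The deposited table holds 13036 genes by Entrez identifier and symbol, with 1 column per library, and its values are log2 CPM (read counts scaled to a common library size) with a small prior. The lowest value and the steps between low values gave a prior of 0.0522 CPM, equal to 2 reads in a library of mean size. After removal of the prior, 100% of values lay within 0.1 read of a whole number of reads. The recovered reads summed to 31645935 and 43542999 in regular culture at 1 h, 40147363 and 33740886 in treated cells at 1 h, 45811965 and 43081914 in regular culture at 7 h, and 27731776 and 37032500 in treated cells at 7 h. The library sizes behind the deposited CPM were 1.04 to 1.05 times these sums in regular culture, 1.09 times in treated cells at 1 h and 0.838 and 0.846 times in treated cells at 7 h, so a scaling between libraries was already applied. Levels are printed as CPM on this deposited scale with the prior removed. A level of 3 reads, the limit that a count of 0 allows, lay between 0.0626 and 0.129 CPM. Intervals of ratios of reads cover counting error only, at the 95% level.

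Column headings name the group and not the replicate, so libraries of a group are called A and B without order, and no column was left unassigned. A reference table of human genes matched 12970 of the identifiers, and 97 of its symbols differed from those in the file; 64 genes had no symbol in the file. Genes or list members outside the table were not analysed here.

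Genes with at least 1 CPM in at least 2 libraries were kept, which removed 8 and left 13028. The deposited log2 values were fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 8 libraries and an intensity trend (4 residual degrees of freedom, 14.5 prior degrees of freedom, median residual SD 0.0587). A pseudocount of 0.5 CPM had been planned for linear values and was not added, because the values were on a log scale. 4 contrasts were tested: treated minus regular culture at 1 h, the same at 7 h, the difference between these, and regular culture at 7 h minus 1 h. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the scale of log2 CPM with the prior, which understates the change of genes with few reads.

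The tests, the gene lists and the rule for named genes were set before the data were examined. By that rule the text draws on the 8 largest rises and 8 largest falls at each time among genes that passed, reached 5 CPM in the higher group and had groups that did not overlap, leaving out pseudogenes and clone names. It also takes TXNRD1, SLC7A11, WWTR1, TXNIP, HMOX1, ATF4, DDIT3, CCN1, CCN2, ACTB and GAPDH whatever their result, and up to 2 rising and 2 falling members of each list that was called or had at least 25% of its members past the threshold. For regular culture the 3 largest changes in each direction were taken, and for the difference between times the 4 largest. Exceptions are named as such where they appear, and results for a few genes are not reported here.

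The 28 gene lists covered NRF2 targets, the ATF4 and integrated stress response, ER chaperones, heat shock proteins, metallothioneins, immediate early genes, YAP/TAZ targets, glycolysis, hypoxia targets, MondoA targets, the pentose phosphate pathway, thioredoxin and glutathione systems, disulfidptosis, actin and adhesion, cholesterol synthesis, mitosis, DNA replication, p53 targets, NF-kB and inflammatory genes, the proteasome, autophagy, ribosome biogenesis, cytosolic ribosomal proteins, mitochondrially encoded genes, nuclear oxidative phosphorylation genes, mesenchymal glioblastoma markers, neural cell markers, and immune, endothelial, epithelial and erythroid markers. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 28 lists. Counts over all tested genes are given beside counts adjusted over the list alone. Some genes belong to several lists.

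The procedure was tested on simulated reads for 12684 genes, with the real libraries' sizes and the mean levels of regular culture at 7 h in every library. The spread between libraries was fixed (dispersion 0.0015), and only a small part of the genes was changed. The wide changes and the scaling differences of the real 7 h libraries were not simulated, so these rates may not carry over to the real calls. At 7 h it recovered 35 of 49 genes changed 1.25-fold (71.4%), 45 of 49 changed 1.5-fold (91.8%), 48 of 48 changed 2-fold and 50 of 50 changed 4-fold, with 8 false calls, and with 0 false calls at 1 h.

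Alternatives were other pseudocounts, no filter and a stricter one, median centring, quantile normalization, only the groups compared, no intensity trend, a test against a minimum change of 1.5-fold, leaving out each library, and for lists an estimated correlation and fry. Scaling to the total of the listed genes, a pseudocount of 0.5 CPM, voom weights on the recovered reads and quantile normalization for the lists were added after seeing the data. Tables were handled with Python 3.11.15, pandas 2.3.3 and NumPy 2.4.6, and plots drawn with matplotlib 3.10.9.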

Results

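RNA was sequenced from LN229-TAZ(4SA), a human glioblastoma cell line named for a form of TAZ, a transcriptional co-activator of the Hippo pathway. Cells were held without glucose in the presence of AF at 1 µM, or in regular culture without AF, and RNA was collected at 1 h or 7 h. This gave 4 groups of 2 libraries. The labels name AF only by its abbreviation, and the series title is about inhibition of thioredoxin reductase 1, the enzyme encoded by TXNRD1. AF and the loss of glucose were applied together, so the effect of each alone cannot be read from these libraries. Between 27731776 and 45811965 reads per library lay in the 13036 listed genes, and 1 read was worth 0.0209 to 0.0430 CPM. The libraries of each pair differed by more than counting error, with a chi-square of 2.85 to 3.63 per degree of freedom. Each library was counted as a separate sample, which this excess alone does not establish. Nothing in the labels says that they came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Levels below are the mean CPM ± SD (n = 2), and each log2 fold change is treated minus regular culture with its standard error (SE).

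The 1 h comparison addressed the early response to AF and glucose deprivation together, against regular culture. HMOX1, which encodes the haem-degrading enzyme heme oxygenase 1, rose from 11.7 ± 0.107 to 2025 ± 62.1 CPM (log2 fold change 7.43, SE 0.05; limma adjusted p = 6.37e-26). HSPA6, a strictly inducible HSP70 gene, rose from 0.919 ± 0.205 to 273 ± 24.2 CPM (log2 fold change 8.15, SE 0.09). Members of the ATF4 and integrated stress response list were also among the largest rises. DDIT4, an inhibitor of mTORC1 signalling, reached 593 ± 19.1 CPM from 26 ± 1.89, CHAC1, which degrades glutathione, reached 134 ± 1.21 from 13.7 ± 0.886, and DDIT3, which encodes the transcription factor CHOP, reached 405 ± 0.955 from 47.3 ± 0.659. The immediate early gene FOS rose by 3.44 log2 units. PCGF2 rose by 4.46 log2 units to 6.76 ± 3.30 CPM, with a wide gap between its treated libraries (4.98 without A and 3.95 without B), and SLC7A11-AS1 rose by 3.27, although reads of this antisense gene cannot be told from those of SLC7A11 in a library without strand marks.

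Members of the YAP/TAZ target list and of the NF-kB and inflammatory list were among the largest falls at 1 h. CCN2, a matricellular growth factor, went from 1306 ± 34.3 to 58.0 ± 0.0342 CPM (log2 fold change -4.49, SE 0.03; limma adjusted p = 5.12e-25). The chemokine gene CXCL8 went from 469.9 ± 0.118 to 9.38 ± 1.13 CPM and CXCL1 from 93.0 ± 0.896 to 5.57 ± 0.360. EDN1, which encodes the vasoconstrictor peptide endothelin 1, changed by -5.80 log2 units, DEPP1 by -3.92, SPOCD1 by -3.66 and BIRC3, an inhibitor of apoptosis, by -3.54. ANKRD1 was covered by 711 reads in the regular libraries and 8 in the treated ones, a level 91.6-fold lower with a 95% counting interval of 46.2 to 213. Many of these genes were also low in regular culture at 7 h, where CCN2 stood at 89.0 ± 1.65 CPM and CXCL8 at 13.6 ± 0.998. Of the 265 genes at least 2-fold lower at 1 h, 149 were also at least 2-fold lower in regular culture at 7 h than at 1 h.

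Genes named in advance for their link to the treatment moved unequally at 1 h. SLC7A11, the cystine importer, rose by 1.00 log2 units (SE 0.05) to 161 ± 4.64 CPM, and ATF4, a master regulator of amino acid stress genes, rose by 0.44. TXNIP, an inhibitor of thioredoxin, fell by 0.43 log2 units and CCN1, a matricellular relative of CCN2, fell by 3.13. ACTB, the main non-muscle actin gene, changed by -0.72 log2 units. TXNRD1 did not pass the test, at 404 ± 3.87 CPM in regular and 418 ± 11.1 in treated cells (limma adjusted p = 0.212), but it was called higher under quantile normalization (0.13) and under scaling to the total of the listed genes (0.12). WWTR1, which encodes TAZ and whose transgene reads cannot be told apart here, differed by -0.06 (adjusted p = 0.162). GAPDH differed by 0.07 (adjusted p = 0.0677), and it was called higher without treated library A (0.10), under quantile normalization (0.44), under scaling to the total of the listed genes (0.14) and with voom weights.

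Of the 28 fixed gene lists, 3 were called higher and 8 lower at 1 h by camera with a preset correlation. The balance depended on the scaling, with 10 higher and 5 lower under quantile normalization and 7 higher and 6 lower under scaling to the total of the listed genes. Of 24 measured heat shock proteins and co-chaperones, 23 rose and none fell (23 adjusted over the list alone), with a median log2 fold change of 0.81 (camera adjusted p = 6.48e-31). ZFAND2A, an inducible partner of the proteasome, rose by 2.64 on the log2 scale. Among 39 genes of the ATF4 and integrated stress response, 32 rose and 2 fell (35 adjusted over the list alone; camera adjusted p = 4.47e-17). The ones that fell were SLC7A1 (-0.54), an arginine transporter, and ATF5 (-0.38). Of 36 NRF2 targets, genes of antioxidant defence, 22 rose and 1 fell (23 adjusted over the list alone; camera adjusted p = 2.03e-11). OSGIN1 rose by 2.27, whereas the long non-coding RNA LUCAT1 changed by -0.48 and lost its call when regular library A or treated library B was left out (-0.41 and -0.40). These 3 lists kept their calls with an estimated correlation, each at an adjusted p = 0.0145.

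Another 8 lists were called lower at 1 h. In the NF-kB and inflammatory list, 18 of 20 genes fell, 13 of them at least 2-fold (18 adjusted over the list alone; median -1.90; camera adjusted p = 2.43e-21, and 0.0145 with an estimated correlation). 19 of 23 YAP/TAZ targets fell (19 adjusted over the list alone; median -0.57; adjusted p = 5.97e-19, and 0.0213 with an estimated correlation). The other 6 lists lost their calls with an estimated correlation. In the actin cytoskeleton and adhesion list, 27 of 32 genes fell (27 adjusted over the list alone; adjusted p = 1.73e-16, and adjusted p = 0.108 with an estimated correlation). Among them, CNN1, a smooth muscle calponin, changed by -2.66 and SRF, the transcription factor of many actin genes, by -2.30. Immediate early genes split, with 19 of 29 lower and 9 higher (28 adjusted over the list alone; adjusted p = 2.69e-04, and adjusted p = 0.506 with an estimated correlation). ARC (-2.97) and BTG2 (-2.15) were lower, while FOS (3.44) and EGR1 (1.49) were higher. Of 21 p53 targets, 12 fell, among them GADD45A (-1.16), and 3 rose, among them SESN2 (2.13), a stress-induced sestrin (15 adjusted over the list alone; adjusted p = 7.96e-04, and adjusted p = 0.112 with an estimated correlation).

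The remaining lower lists moved less. 8 of 13 mitochondrially encoded genes fell and ND4 rose by 0.12, a call lost without regular library A (0.07) or treated library B (0.11) (10 adjusted over the list alone; adjusted p = 0.00601, and adjusted p = 0.601 with an estimated correlation), with ND2 at -0.60 and ND1 at -0.53. 10 of 24 ribosome biogenesis genes fell, such as RRS1 (-0.58) and RRP12 (-0.54), and 3 rose, such as POLR1B (0.23) and NOB1 (0.22) (13 adjusted over the list alone; adjusted p = 0.0244, and adjusted p = 0.506 with an estimated correlation). That call was also lost without regular 1 h library B (adjusted p = 0.167) or treated 1 h library A (adjusted p = 0.0525). 8 of 18 mesenchymal glioblastoma markers fell, led by THBS1 (-2.26), a matricellular glycoprotein (9 adjusted over the list alone; adjusted p = 0.0101, and adjusted p = 0.506 with an estimated correlation), and the list median turned from -0.06 to 0.01 under quantile normalization and 0.01 under scaling to the total.

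17 lists were not called at 1 h. Members went both ways among ER chaperones and unfolded protein response genes (5 rose and 5 fell of 24; 11 adjusted over the list alone), glycolysis genes (3 and 7 of 23; 11 adjusted over the list alone), hypoxia targets (6 and 4 of 17; 11 adjusted over the list alone) and autophagy and lysosome genes (11 and 5 of 27; 17 adjusted over the list alone). HERPUD1, a component of ER-associated degradation, rose by 1.43, SLC2A3, a glucose transporter, by 0.92 and the autophagy receptor SQSTM1 by 0.64. The thioredoxin, glutathione and peroxiredoxin list had 5 rises and 3 falls among 31 genes (8 adjusted over the list alone), and the pentose phosphate and NADPH list 6 rises and no fall among 13 (7 adjusted over the list alone). The disulfidptosis list had 3 rises among 15 (3 adjusted over the list alone). Rises and falls numbered 5 and 4 of 23 cholesterol synthesis genes (9 adjusted over the list alone), 5 and 6 of 25 mitosis genes (11 adjusted over the list alone), and 3 and 10 of 26 DNA replication genes (13 adjusted over the list alone). They numbered 2 and 3 of 31 proteasome subunits (4 adjusted over the list alone), 2 and 1 of 48 cytosolic ribosomal proteins (2 adjusted over the list alone), and 1 and 5 of 31 nuclear oxidative phosphorylation genes (3 adjusted over the list alone). In the MondoA list 1 of 4 rose, ARRDC3 (2.23), and TXNIP fell (2 adjusted over the list alone), and in the metallothionein and zinc export list SLC30A1 (-0.64) was the 1 of 4 that fell (1 adjusted over the list alone). Of 10 astrocyte, oligodendrocyte and neuron markers 3 rose and 1 fell (4 adjusted over the list alone), and none of 3 immune, endothelial, epithelial and erythroid markers passed (0 adjusted over the list alone). These counts depended on the scaling. Under quantile normalization and under scaling to the total of the listed genes, rises and falls numbered 27 and 1, and 24 and 1, of cytosolic ribosomal proteins, and both scalings called that list, the pentose phosphate, the disulfidptosis and the autophagy lists higher. Quantile normalization also called higher proteasome subunits (13 rises and 0 falls), thioredoxin and glutathione systems (14 and 2) and ER chaperones (12 and 3). Median and mean had opposite signs in the MondoA list (-0.07 and 0.42), the disulfidptosis list (-0.02 and 0.12) and the cholesterol list (0.01 and -0.01).

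In all, 4997 of 13028 tested genes passed a limma adjusted p of 0.05 at 1 h, 2303 higher and 2694 lower, of which 143 and 265 changed at least 2-fold. Higher genes made up 46.1% of the calls, against 57.8% under quantile normalization and 68.4% under scaling to the total of the listed genes. Requiring a change above 1.5-fold left 463 genes.

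**Figure D1:**
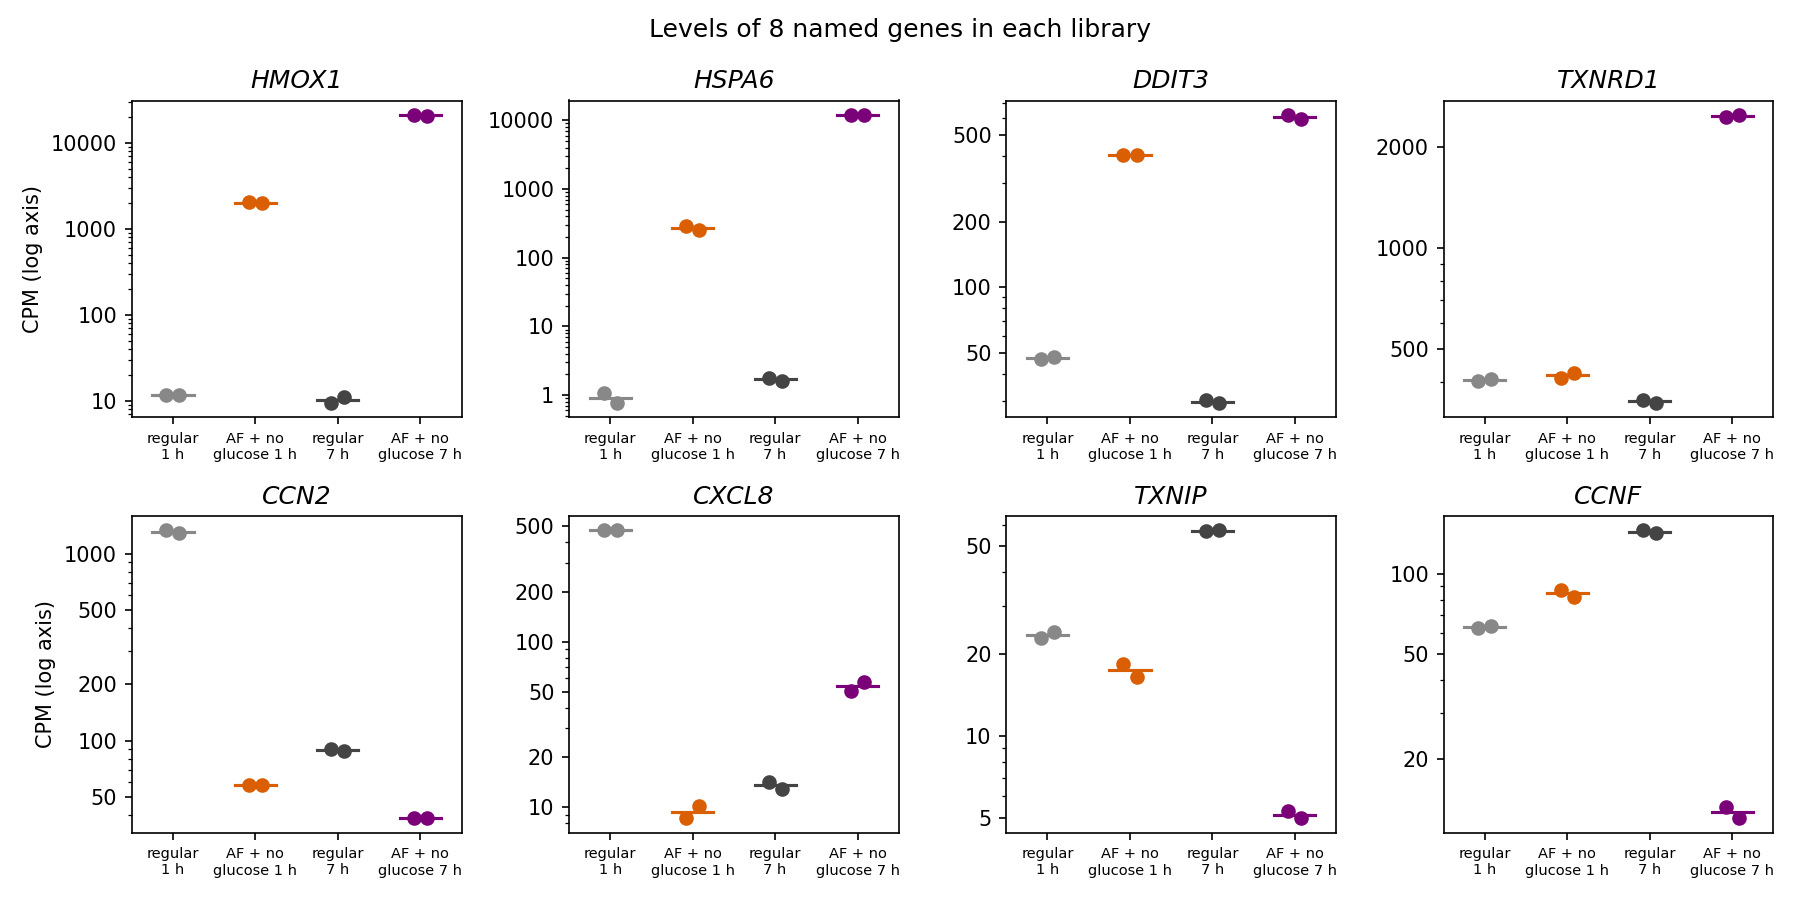
CPM of 8 genes in each of the 8 libraries on log axes, with 2 points per group and a line at their mean. HMOX1 and HSPA6 were higher in treated cells at both times, TXNRD1 was higher at 7 h (from 351 to 2473 CPM), and CCN2 and CXCL8 were far higher in regular culture at 1 h than in the other 3 groups.

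The 7 h comparison addressed the late response. HMOX1 rose from 10.3 ± 1.18 to 21074 ± 289.7 CPM (log2 fold change 11, SE 0.05; limma adjusted p = 4.44e-29) and took up 1.77% to 1.78% of the reads in listed genes. HSPA6 rose from 1.70 ± 0.1 to 11891 ± 141 CPM (log2 fold change 12.73, SE 0.09). Its reads may be shared with HSPA7, a closely similar pseudogene named here after its values were seen, which rose by 11.40 log2 units. GDF15, a stress-induced cytokine, went from 4.66 ± 0.122 to 654 ± 11.3 CPM and ZFAND2A from 17.5 ± 1.26 to 2099 ± 4.48. The phosphatase gene DUSP2 rose by 6.66 log2 units, FOS by 6.33 and the serine protease gene HTRA3 by 7.00. PNLDC1 had 3 reads in the regular and 1034 in the treated libraries, a ratio of 588.8 with a 95% counting interval of 201 to 2860.

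Falls at 7 h were smaller. TXNIP went from 56.9 ± 0.293 to 5.14 ± 0.222 CPM (log2 fold change -3.46, SE 0.07; limma adjusted p = 2.37e-19), and CCNF, which encodes cyclin F, from 144 ± 2.47 to 12.6 ± 0.886. HILPDA, a lipid droplet protein gene, changed by -3.30 log2 units, TMEM177 by -3.25, B3GALT2 by -3.15 and the long non-coding RNA BLACAT1 by -3.34. SNORA73A (-3.95), which lies inside its host gene SNHG3, and TRNH (-3.14), a mitochondrial tRNA gene, had values that can hold reads of the transcripts around them.

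Of the genes named in advance, TXNRD1 rose at 7 h from 351 ± 4.90 to 2473 ± 21 CPM (log2 fold change 2.82, SE 0.03; limma adjusted p = 9.85e-24), SLC7A11 from 41.8 ± 1.66 to 417 ± 38.7, DDIT3 from 29.9 ± 0.525 to 605 ± 18.2 and ATF4 from 326 ± 0.577 to 807 ± 13.1. ACTB changed by -1.23, CCN2 by -1.20 and CCN1 by -0.17. WWTR1 was called higher by 0.30 and GAPDH by 0.53, but WWTR1 turned to -0.02 under scaling to the total of the listed genes and GAPDH to -0.67 under quantile normalization.

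Of 14 lists called higher at 7 h, 4 hold protein quality control genes, and 3 of these lost the call with an estimated correlation. All 24 heat shock proteins and co-chaperones rose at least 2-fold (24 adjusted over the list alone; median 3.51; camera adjusted p = 2.91e-17, and 0.0385 with an estimated correlation), and their share of the reads was 10.6% to 10.7%, against 1.16% to 1.18% in regular culture. HSP90AA1, named after its values were seen, took more reads than any other listed gene in both treated 7 h libraries, at 22779 ± 115 CPM. 29 of 31 proteasome subunits rose, with PSMD12 at 1.28 and PSMD14 at 1.24, and PSMD5 fell (-0.98) (30 adjusted over the list alone; adjusted p = 2.28e-09, and adjusted p = 0.222 with an estimated correlation). 22 of 24 ER chaperone and unfolded protein response genes rose, led by HERPUD1 (3.58) and the ER stress sensor ERN1 (3.54) (22 adjusted over the list alone; adjusted p = 1.71e-08, and adjusted p = 0.119 with an estimated correlation). In the autophagy and lysosome list 22 of 27 rose, such as GABARAPL1 (4.40) and SQSTM1 (3.01), and 1 fell, ULK1 (-0.18) (23 adjusted over the list alone; adjusted p = 1.43e-06, and adjusted p = 0.109 with an estimated correlation). The ULK1 call was lost without regular library B (-0.17) or treated library A (-0.12). Under scaling to the total of the listed genes, rises and falls numbered 26 and 4 of the proteasome subunits, 19 and 2 of the ER list and 18 and 5 of the autophagy list, and under quantile normalization 17 and 4 of the ER list.

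4 lists of antioxidant and amino acid stress genes were called higher as well. Regular levels at 7 h lay a median of -0.27 (NRF2 targets) and -0.22 (ATF4 genes) from those at 1 h. 34 of 36 NRF2 targets rose, 28 of them at least 2-fold (36 adjusted over the list alone; adjusted p = 6.02e-14, and 0.0219 with an estimated correlation), and the transporter gene ABCC3 (-0.72) and the reductase gene CBR3 (-0.37) fell. 38 of 39 ATF4 and integrated stress response genes rose, with ATF3 at 5.59, and ATF5 fell (-0.92) (39 adjusted over the list alone; adjusted p = 1.96e-16, and 0.0219 with an estimated correlation). In the thioredoxin, glutathione and peroxiredoxin list 22 of 31 rose, led by SRXN1 (3.37), the sulfiredoxin gene, and GCLM (2.88), of glutathione synthesis, and 6 fell, including TXNRD3 (-1.04) (28 adjusted over the list alone; adjusted p = 4.97e-04, and adjusted p = 0.175 with an estimated correlation). Its median of 0.41 became 0.0949 under scaling to the total of the listed genes, with 17 rises and 9 falls. The disulfidptosis list, in which SLC7A11 and its partner subunit SLC3A2 (2.05) led, had 11 rises and 4 falls among 15 genes and a median of 0.28 that turned to -0.04 under scaling to the total of the listed genes (15 adjusted over the list alone; adjusted p = 0.0245, and adjusted p = 0.245 with an estimated correlation). Several lists share members, SLC7A11 and TXNIP among them.

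Another 4 lists were called higher on the deposited scaling, some by small margins. 12 of 17 hypoxia targets rose, such as NDRG1 (2.42) and VEGFA (2.41), and 3 fell (15 adjusted over the list alone; adjusted p = 0.00773, and adjusted p = 0.150 with an estimated correlation). 18 of 23 glucose transport and glycolysis genes rose, led by SLC2A3 (3.08), and 2 fell, SLC16A3 (-0.27) and LDHA (-0.19), but the list median turned from 0.23 to -0.09 under scaling to the total of the listed genes, with 8 higher and 11 lower (20 adjusted over the list alone; adjusted p = 0.00143, and adjusted p = 0.222 with an estimated correlation). 24 of 31 nuclear oxidative phosphorylation genes rose and 3 fell, with a median that turned from 0.27 to -0.05 under the same scaling, with 5 higher and 14 lower (27 adjusted over the list alone; adjusted p = 0.00412, and adjusted p = 0.245 with an estimated correlation). All 48 cytosolic ribosomal protein genes rose, by a median of 0.48, or 0.16 with 38 higher and 1 lower under that scaling (48 adjusted over the list alone; adjusted p = 5.53e-12, and adjusted p = 0.245 with an estimated correlation).

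Immediate early genes, 26 of 29, rose at 7 h with a median of 2.19 (26 adjusted over the list alone; adjusted p = 1.13e-12, and adjusted p = 0.176 with an estimated correlation). FOSB went from 1.19 ± 0.0595 to 88.2 ± 5.42 CPM, still below its 329.5 ± 38.7 in regular culture at 1 h. Among 10 measured astrocyte, oligodendrocyte and neuron markers, 8 rose and 1 fell (9 adjusted over the list alone; adjusted p = 0.0188, and adjusted p = 0.234 with an estimated correlation). RBFOX3, which encodes the neuronal antigen NeuN, reached 26.9 ± 2.49 CPM and SOX10, a glial lineage factor, went from 970.1 ± 25.8 to 196 ± 5.25.

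5 lists were called lower at 7 h. All 25 mitosis genes were lower, 21 of them at least 2-fold, with a median of -1.63 (25 adjusted over the list alone; camera adjusted p = 2.63e-13, and adjusted p = 0.119 with an estimated correlation). The proliferation marker MKI67 went from 1240.4 ± 37.2 to 226 ± 13.6 CPM and the mitotic kinase gene AURKA from 288 ± 2.63 to 54.0 ± 2.42. 19 of 26 DNA replication genes fell, such as E2F2 (-2.67) and GINS1 (-2.05), while 4 rose, including CDC6 (0.89) (23 adjusted over the list alone; adjusted p = 4.97e-04, and adjusted p = 0.295 with an estimated correlation). 19 of 24 ribosome biogenesis genes fell, such as POLR1A (-1.25), and 3 rose, including NOP58 (1.13) (22 adjusted over the list alone; adjusted p = 0.00357, and adjusted p = 0.245 with an estimated correlation). 22 of 32 actin cytoskeleton and adhesion genes fell, with CD2AP at -1.42, and 5 rose, with PDLIM1 at 0.60 (27 adjusted over the list alone; adjusted p = 9.63e-04, and adjusted p = 0.295 with an estimated correlation). 17 of 23 YAP/TAZ targets fell, such as FJX1 (-1.98) and ARHGEF17 (-1.97), and 5 rose, such as ANKRD1 (3.43) and GADD45A (2.78) (22 adjusted over the list alone; adjusted p = 0.0108, and adjusted p = 0.245 with an estimated correlation). That call ended under scaling to the total of the listed genes (adjusted p = 0.0922).

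At 7 h 9 lists were not called. Rises and falls numbered 9 and 10 of 21 p53 targets (20 adjusted over the list alone), with SESN2 at 4.95, BBC3 at 2.91 and SESN1 at -1.69. They numbered 7 and 10 of 20 NF-kB and inflammatory genes (17 adjusted over the list alone), with PTGS2, the inducible cyclooxygenase gene, at 5.95 and CCL2 at -1.57. Likewise 8 rose and 5 fell of 13 pentose phosphate and NADPH genes (13 adjusted over the list alone), with ME1 (2.10) and PGD (1.81) the furthest up. The counts were 12 and 6 of 23 cholesterol synthesis genes (19 adjusted over the list alone), turning to 8 and 11 under scaling to the total of the listed genes, and 5 and 6 of 13 mitochondrially encoded genes (11 adjusted over the list alone), the last with 0 and 11 under quantile normalization. Mesenchymal markers had 10 rises and 5 falls of 18 (15 adjusted over the list alone), but 5 rises and 11 falls under quantile normalization and under scaling to the total, where the median of 0.12 turned to -0.44 and -0.20. ND4 (0.51) and COX2 (0.42), here the mitochondrial subunit gene, turned to -0.70 and -0.59 under quantile normalization, which called the mitochondrially encoded list lower (adjusted p = 3.15e-05). In the metallothionein list MT1E (-1.27) and MT1X (-1.24) were among 3 of 4 that fell (4 adjusted over the list alone), and in the MondoA list 2 of 4 rose and TXNIP fell (3 adjusted over the list alone). Of 3 immune, endothelial, epithelial and erythroid markers 2 rose, VWF (1.48 CPM) and CD68 (21.6 CPM), and KRT14 fell (3 adjusted over the list alone). Median and mean differed in sign in the MondoA (0.26 and -0.14), NF-kB (-0.24 and 0.26) and mitochondrially encoded (0.01 and -0.18) lists.

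In all, 10630 genes passed at 7 h, 5280 higher and 5350 lower, of which 1381 and 1494 changed at least 2-fold, and 4071 genes passed a test for a change above 1.5-fold. Scaling to the total of the listed genes moved the median of all tested genes at 7 h from -0.01 to -0.32 log2 units and the share of higher genes among the calls from 49.7% to 29.3%. Genes at least 2-fold higher and lower then numbered 904 and 2534, so the balance of rises and falls is relative to the scaling in use.

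**Figure D2:**
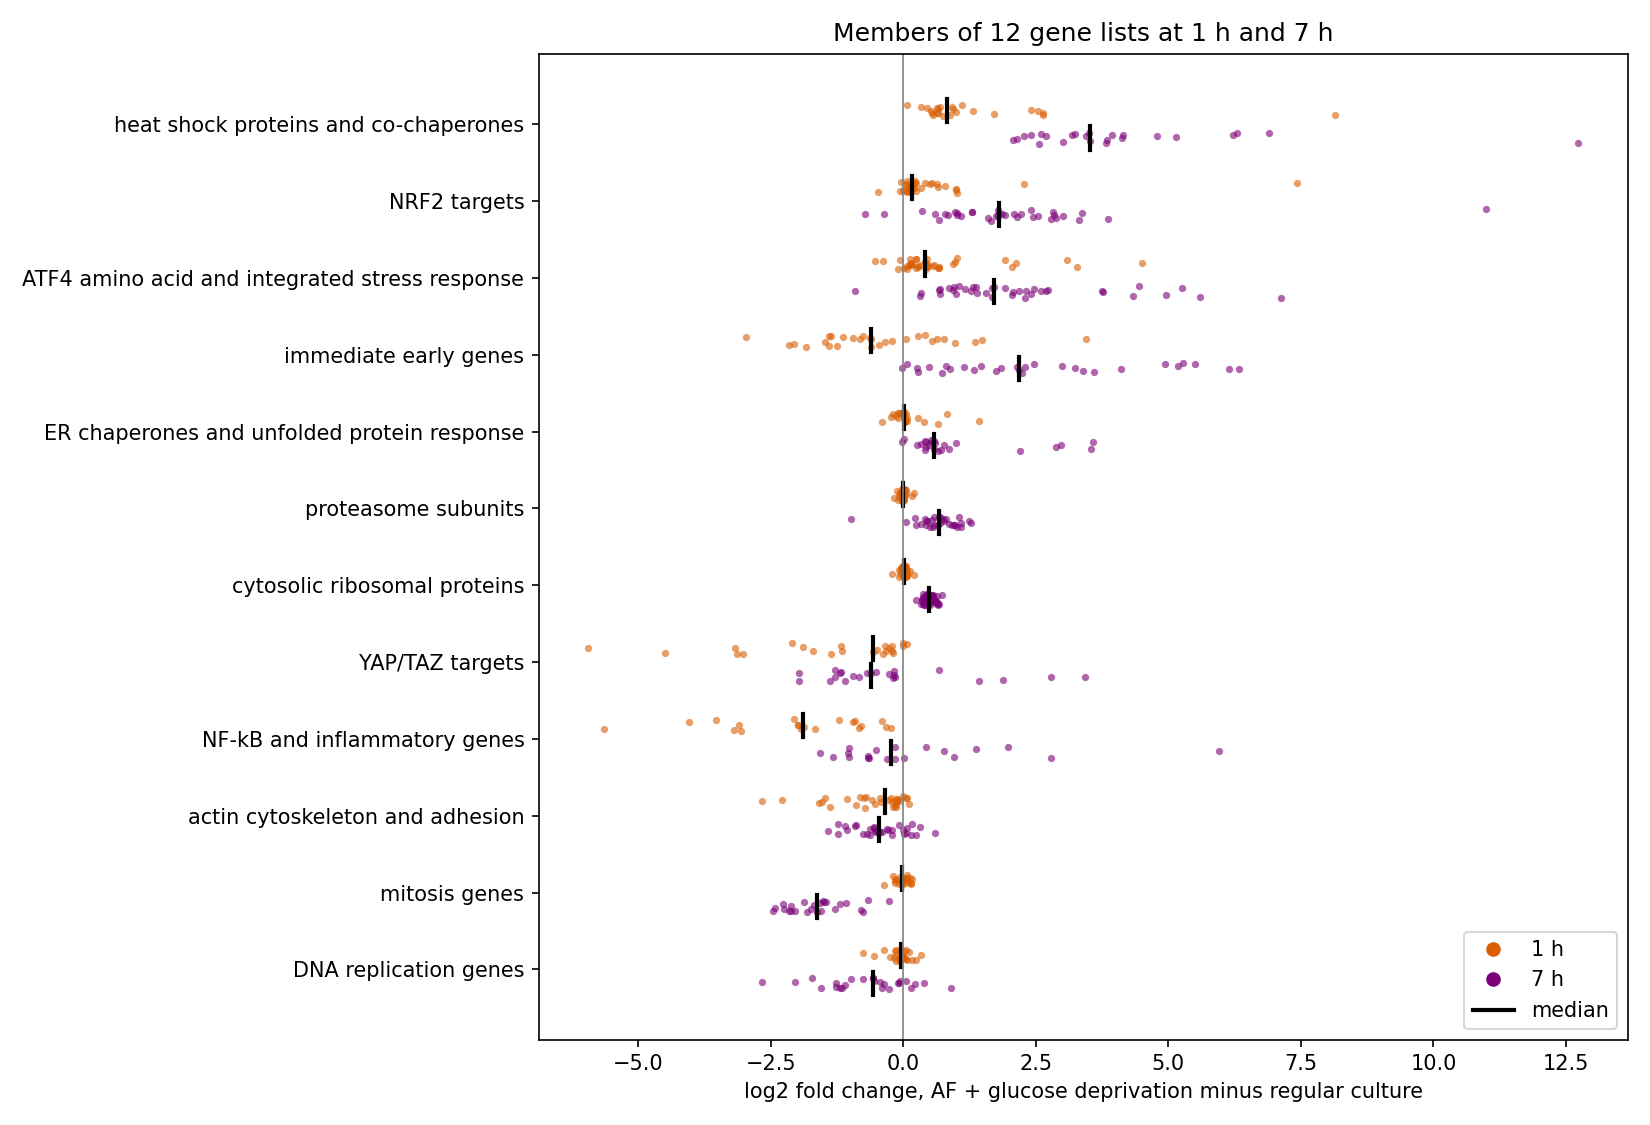
Log2 fold change of each measured member of 12 gene lists at 1 h (orange) and 7 h (purple), with each list's median as a black bar. Heat shock genes lay above 0 at both times (medians 0.81 and 3.51), immediate early genes had medians of -0.62 and 2.19, and mitosis genes had a median of -1.63 at 7 h.

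Whether the response grew or shrank with time was tested as the difference between the 7 h and 1 h fold changes. ANKRD1 differed most, from -5.94 at 1 h to 3.43 at 7 h (difference 9.38, SE 0.32; limma adjusted p = 1.81e-15). ARC, a neuronal immediate early gene, differed by 8.25, CXCL8 by 7.62 and the nuclear receptor gene NR4A3 by 7.25. In each of these 4 genes the level in regular culture dropped between 1 h and 7 h, for NR4A3 from 147 ± 17.1 to 0.867 ± 0.102 CPM. The largest negative differences were in TMEM177 (-4.04), CCNF (-3.93), HILPDA (-3.85) and HOXB-AS3 (-3.66), the last an antisense gene whose reads cannot be told from those of its neighbours. In each of these 4 genes the level in regular culture rose between 1 h and 7 h, which makes up part of the difference. For TMEM177 the regular libraries went from 6.02 and 5.71 to 16.1 and 16.7 CPM. TXNRD1 differed by 2.77 (adjusted p = 1.14e-20) and HMOX1 by 3.57, whereas THBS1 did not pass (difference 0.01, adjusted p = 0.870).

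The difference passed for 9606 genes, 4783 positive and 4823 negative, and 3646 differed by more than 1.5-fold. Positive differences made up 49.8% of the calls and 24.9% under scaling to the total of the listed genes. For 1738 genes the fold changes at both times passed with opposite signs. Of the genes changed at least 2-fold, 95 were higher at both times (15.2 expected for independent lists), 68 were lower at both (30.4 expected) and 69 were lower at 1 h and higher at 7 h (28.1 expected). In the other direction, 8 were higher at 1 h and lower at 7 h. The 149 genes at least 2-fold lower at 1 h and also in regular culture at 7 h had medians of -1.66 at 1 h and 0.68 at 7 h. The 1 h and 7 h comparisons share no library, but both are set against regular culture, which itself changed between the times. Among 4355 genes called at both times 60.1% moved the same way. Across genes, which are not independent replicates, Pearson's r of the fold changes was 0.22.

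**Figure D3:**
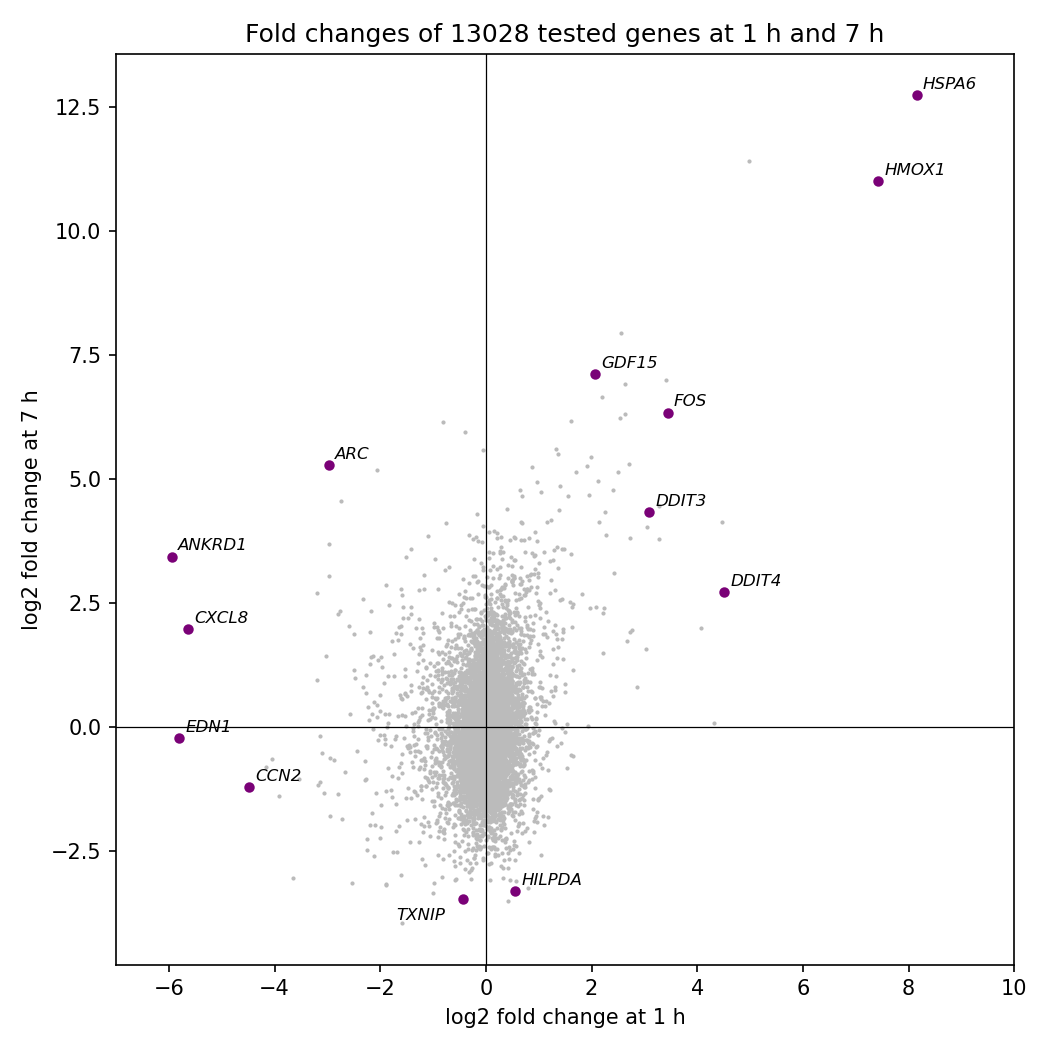
Log2 fold change at 7 h against that at 1 h for the 13028 tested genes (grey), with 13 named genes in purple. HSPA6 and HMOX1 lie at the upper right (12.73 and 11 at 7 h), and ANKRD1, CXCL8 and ARC lie at the upper left, lower at 1 h and higher at 7 h.

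Regular culture itself changed between 1 h and 7 h, and this background bears on both comparisons. FOSB went from 329.5 ± 38.7 to 1.19 ± 0.0595 CPM (log2 fold change -8.05, SE 0.06; limma adjusted p = 5.15e-25), NR4A3 changed by -7.32 and EGR4 by -6.59. EGR4 had 786 reads in the 1 h and 5 in the 7 h libraries, a level 187.6-fold lower with a 95% counting interval of 80.1 to 579.4, and the fitted value understates this fall because of the prior. 28 of 29 immediate early genes, 18 of 20 NF-kB and inflammatory genes, 18 of 23 cholesterol synthesis genes and 14 of 23 YAP/TAZ targets were lower at 7 h (29, 18, 19 and 23 changed in either direction adjusted over the list alone). Those 4 lists had camera adjusted p of 4.10e-29, 2.79e-12, 4.71e-08 and 0.0455, and they did not hold with an estimated correlation (adjusted p = 0.0791, 0.0791, 0.232 and 0.441). 23 of 24 ribosome biogenesis genes were higher (24 adjusted over the list alone; adjusted p = 7.58e-12, and adjusted p = 0.0791 with an estimated correlation). 4 lists that rose with treatment at 7 h were lower in regular culture at 7 h than at 1 h, with falls in 27 of 36 NRF2 targets (30 adjusted over the list alone; adjusted p = 7.06e-06), 21 of 39 ATF4 genes against 9 rises (30 adjusted over the list alone; 0.00245), 15 of 24 ER chaperones (16 adjusted over the list alone; 0.00286) and 13 of 17 hypoxia targets (16 adjusted over the list alone; 0.0186). With an estimated correlation their adjusted p = 0.0791, 0.184, 0.350 and 0.184. 15 of 21 p53 targets fell (16 adjusted over the list alone; adjusted p = 5.25e-06, and adjusted p = 0.0791 with an estimated correlation). Rises were seen in 42 of 48 cytosolic ribosomal proteins (44 adjusted over the list alone; adjusted p = 3.84e-07), 14 of 25 mitosis genes (17 adjusted over the list alone; 0.00245) and 17 of 26 DNA replication genes (19 adjusted over the list alone; also called), with adjusted p = 0.461, 0.441 and 0.451 with an estimated correlation. CORO2B, a coronin, rose by 3.41 log2 units to 7.14 ± 0.584 CPM and AJAP1 by 2.74 to 5.40 ± 0.213. RNH1 had the largest fitted rise, 4.06, but rested on library B, with 63 reads in regular 7 h library A and 615 in B, and its rise was 2.41 without B and 5.72 without A. In all, 8013 genes differed between the times, 4006 higher and 4007 lower at 7 h, of which 202 and 612 changed at least 2-fold, and 964 passed a test for a change above 1.5-fold.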

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

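The tests of the 265 genes lower at 1 h were chosen only after the result was seen, while the test of the difference between times was planned.

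The treatment's effect differed between 7 h and 1 h for 9606 genes by the planned limma test of the difference. Of the genes named at either time, 143 differed. Values are given here only for genes among those that passed at both times with opposite signs and for those with the largest differences, as the log2 fold change at 7 h minus that at 1 h. Each difference also holds the change of regular culture between the times. In treated libraries NR4A3 stood at 34.4 and 35.8 CPM at 1 h and at 32.3 and 34.5 at 7 h. Its regular libraries went from 159 and 135 to 0.939 and 0.794 CPM. Treated FOSB fell, from 190 and 183 to 92.1 and 84.4 CPM, whereas treated ARC rose, from 9.52 and 8.44 to 49.4 and 45.6.

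Among stress, signalling and inflammatory genes the difference was 9.38 for ANKRD1, 8.25 for ARC, 7.62 for CXCL8, 7.25 for NR4A3, 6.97 for FOSB, 6.35 for PTGS2, 3.94 for GADD45A and 3.69 for CXCL3. It was 2.93 for LUCAT1, 2.41 for BTG2, 1.55 for SOD2 and -2.14 for PLK2. For genes of transport, secretion and metabolism it was 1.35 for ANGPTL4, 1.23 for SLC7A1, 1.20 for PFKFB3, 1.17 for SEC24D, 0.87 for PFKFB4, 0.86 for SLC30A1, 0.43 for CYP51A1 and -0.82 for MVK. COX5B differed by 1.01, RPS15 by 0.93 and DSTN by 0.44. For PSMD12 and PSMD5 the values were 1.46 and -1.17.

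For genes of the cell cycle and growth the difference was -3.93 for CCNF, -3.01 for E2F2, -2.54 for AURKA, -1.43 for TTK, -0.84 for HMMR, -0.50 for CDT1, -1.18 for POLR1B and 1.03 for CDC6. TMEM177 gave -4.04, HILPDA -3.85, HOXB-AS3 -3.66, SOX10 -2.66 and TUBB3 1.20.

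By list, camera called 18 differences. The median difference was 2.55 for heat shock proteins, 1.60 for NRF2 targets and 1.24 for the ATF4 and integrated stress response, and these 3 held with an estimated correlation (adjusted p = 0.0389, 0.0312 and 0.0312). The other 15 lost their calls with it. Those medians were 2.46 for immediate early genes (adjusted p = 0.114 with an estimated correlation), 1.80 for NF-kB and inflammatory genes (0.0802), 1.10 for astrocyte, oligodendrocyte and neuron markers (0.280), 0.86 for hypoxia targets (0.114), 0.65 for proteasome subunits (0.175), 0.56 for ER chaperones (0.0908), 0.45 for autophagy and lysosome genes (0.0802) and 0.41 for thioredoxin and glutathione systems (0.135). They were -1.57 for mitosis genes (0.0802), -0.50 for DNA replication genes (0.307) and -0.28 for ribosome biogenesis genes (0.357). Cytosolic ribosomal proteins had a median difference of 0.45 (0.284). For glycolysis genes (0.35), disulfidptosis genes (0.30) and nuclear oxidative phosphorylation genes (0.25), with adjusted p = 0.158, 0.284 and 0.284 with an estimated correlation, the median turned to -0.04, -0.09 and -0.13 under scaling to the total of the listed genes. Quantile normalization left 0.064, 0.057 and 0.090 for these 3 lists and 0.39 for proteasome subunits. Scaling to the total left 0.063 for autophagy and lysosome genes, 0.021 for thioredoxin and glutathione systems, 0.18 for ER chaperones, 0.48 for hypoxia targets, 0.73 for astrocyte, oligodendrocyte and neuron markers, 0.27 for proteasome subunits and 0.068 for cytosolic ribosomal proteins (17 of 48 higher in place of 48), and quantile normalization left 0.10 for the last (23 of 48 higher). Negative differences grew under scaling to the total, to -1.95 for mitosis genes, -0.89 for DNA replication genes and -0.67 for ribosome biogenesis genes. The calls themselves were not tested under these scalings. The differences also hold the change of regular culture. For immediate early genes the mean difference was 2.95, against a mean of -3.25 for regular culture at 7 h minus 1 h. These means were 2.24 and -1.94 for NF-kB and inflammatory genes, so in both lists the difference came mostly from the fall in regular culture. For heat shock proteins they were 2.74 and -0.01.

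Of the 265 genes at least 2-fold lower at 1 h, 149 (56.2%) were also at least 2-fold lower in regular culture at 7 h than at 1 h, against 12.4 expected for independent lists. In 100 simulations of unchanged groups against the same libraries, 2.02 genes on average were lower in both. Those simulations drew only residual noise, so they cannot show how much overlap the shared libraries create among genes chosen as lower at 1 h. A passing rise of these genes in the regular 1 h libraries may account for part of the fall, and the treated 1 h level lay a median of -0.41 log2 units from the regular 7 h level (quartiles -1.19 and 0.22). Part of the overlap may come from the regular 1 h libraries that both comparisons share, and no sample taken before treatment was analysed here. The choice among the scalings tried did not make these falls, since at least 241 genes were 2-fold lower under each of 3 other scalings. Those scalings moved the median of all tested genes at 1 h by only 0.0010 to 0.068 log2 units. The count could therefore hardly change, and a larger error of scaling was not tested. An effect of the treatment that keeps these genes from rising stays open, as the design has no time before 1 h.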

How the results depend on the processing

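Scaling to the total of the listed genes, a pseudocount of 0.5 CPM, voom and quantile normalization of the lists were chosen only after the data were seen, and the other tests were planned. A test for a change above 1.5-fold left 463 genes at 1 h, 4071 at 7 h, 3646 for the difference between times and 964 in regular culture. Other settings kept each count within 1.5 times its value, and leaving out each library gave 3659 to 5284 genes at 1 h, 9973 to 10652 at 7 h, 9054 to 9436 for the difference and 6759 to 8268 in regular culture; a group left with 1 library was assumed to vary like the others. Of the 4997 calls at 1 h, 71.4% were kept without treated library B and 75.7% without an intensity trend. Under scaling to the total, 79.9% of the 7 h calls were kept and 1168 changed sign, as did 1198 of the differences between times; genes at least 2-fold higher and lower at 7 h were then 904 and 2534 in place of 1381 and 1494. With a pseudocount of 2 CPM, which shrinks changes of genes at low levels, genes changed at least 2-fold numbered 235 in place of 408 at 1 h, 1936 in place of 2875 at 7 h, 2011 in place of 2956 for the difference and 421 in place of 814 in regular culture.

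Of 28 lists, 11 were called at 1 h (10 to 12 when a library was left out), 5 with an estimated correlation and 18 by fry, which does not compare a list with other genes. The 3 higher and 8 lower lists became 10 and 5 under quantile normalization (15 in all) and 7 and 6 under scaling to the total (13). Both scalings added higher calls at 1 h for pentose phosphate (adjusted p = 0.0110 and 0.0267), disulfidptosis (0.0112 and 0.0432), autophagy (0.0214 and 0.0389) and cytosolic ribosomal protein genes (2.09e-04 and 0.0164), and quantile normalization for ER chaperones (0.0214), thioredoxin systems (0.0421) and proteasome subunits (0.0202). At 7 h 19 were called, also when any library was left out, 3 with an estimated correlation and 27 by fry; 12 higher and 6 lower were called under quantile normalization and 12 and 4 under scaling to the total, in place of 14 and 5. Calls gained at 7 h were mitochondrially encoded genes, lower under quantile normalization (3.15e-05), and pentose phosphate genes, higher under scaling to the total (0.0378). Calls lost at 1 h were ribosome biogenesis (adjusted p = 0.104 under quantile normalization and 0.0540 under scaling to the total), mitochondrially encoded genes (0.0694 under quantile normalization) and mesenchymal markers (0.524 and 0.0562). At 7 h, glycolysis (0.642 and 0.136) and disulfidptosis (0.159 and 0.267) lost their calls under both, and nuclear oxidative phosphorylation (0.496) and YAP/TAZ targets (0.0922) under scaling to the total.

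For the named genes, 4030 of 4141 values over 208 gene and comparison pairs kept their direction and side of the threshold, 96 lost the call (71 of them in the test above 1.5-fold), 6 gained it and 9 reversed. All 9 were at 7 h. Under quantile normalization these were GAPDH (-0.67), DSTN (-0.0897), NPM1 (-0.0891), ND4 (-0.70) and COX2 (-0.59), and the cause was not tested. Under scaling to the total these were WWTR1 (-0.0213), SLC30A1 (-0.0929), DSTN (-0.0105) and NPM1 (-0.0218). That scaling moved the median of all tested genes at 7 h by -0.315 log2 units, enough to turn such small rises. Calls that a left-out library ended were LUCAT1, ENO2, HSD17B7, TTK, OPTN and ND4 at 1 h and ULK1 at 7 h.

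No paired analysis was possible because the columns carry no replicate numbers, so the planned fit with a replicate block was not run. The planned edgeR and DESeq2 fits were not run because the deposited values are log2, although whole reads could be recovered, so this was a choice. Voom on the recovered reads called 5202, 10584, 9652 and 8324 genes at 1 h, at 7 h, for the difference and in regular culture. The effect of depth was not tested, and genes near 3 reads, such as PNLDC1 in regular culture, carry wide counting intervals.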

Other observations

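The gene families, and the tests here other than the one for reads from DNA, were chosen only after the results were seen. The 15 families with at least 3 measured genes were tested at 2 times and adjusted together. This adjustment does not cover the choice of families, so their p-values are descriptive only.

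At 7 h all 8 measured subunits of the CCT chaperonin, which folds actin and tubulin, rose, with a median log2 fold change of 0.89 (0.57 under scaling to the total of the listed genes and 0.58 under quantile normalization) and CCT4 the highest at 2.05 (camera adjusted p = 1.46e-04, and adjusted p = 0.440 with an estimated correlation). The polyubiquitin gene UBB rose by 3.04. Of 5 BAG co-chaperone genes 3 rose and 2 fell (camera adjusted p = 0.388), from BAG5 at -1.19 to BAG3 at 6.22. All 8 HOXC genes, developmental transcription factors, fell at 7 h, with a median of -1.31 (camera adjusted p = 0.0125, and adjusted p = 0.440 with an estimated correlation), and 6 of 7 HOXB genes fell while HOXB9 rose by 2.23 (camera adjusted p = 0.0967). Of 7 HOXA genes 5 fell and 0 rose (camera adjusted p = 0.187). Of 34 kinesin (KIF) genes 23 fell and 6 rose (camera adjusted p = 0.00663, and adjusted p = 0.440 with an estimated correlation). KIF23 (-2.12), the lowest of them, also belongs to the mitosis list, so this result is not independent of that list.

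At 1 h, of 423 zinc finger (ZNF) genes, 227 rose and 37 fell, with a median of 0.25 (camera adjusted p = 4.07e-10, and adjusted p = 0.440 with an estimated correlation). At 7 h 128 rose and 214 fell, with a median of -0.20, or -0.51 under scaling to the total of the listed genes (camera adjusted p = 0.225).

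Protein-coding genes with 1 exon were lower at 7 h: 110 of 176 fell and 37 rose, with a median of -0.65 against 0.00 for 11832 genes with several exons. The median was -0.42 for 365 genes with 2 exons, and -0.66 for the 1-exon genes without 8 histone genes. Transcript length, GC content and expression level are argued against as the whole cause, since the median difference from 10 matched genes each was -0.73 (95% bootstrap interval -0.90 to -0.40, 2000 draws). Reads from DNA, present in the regular libraries, were predicted to leave the most highly expressed genes little different from genes with several exons. In the 59 1-exon genes with the highest expression the difference was -0.60 (interval -0.81 to -0.23), so these genes did differ. The test cannot decide on DNA reads, because the bound set for excluding them, -0.3, lies inside that interval. How many reads came from DNA was not estimated, and such reads may still add to the fall. No biological explanation was tested.

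Among genes with a mean below 1 CPM in regular culture at 7 h, 45 rose at least 8-fold, and 15 of these passed the expression filter only through the treated 7 h libraries, so no share of all low genes is given. The 45 include the neuronal gene RBFOX3 (5.60) and DUSP2 (6.66). The largest rise among them was that of the pseudogene HSPA7 (11.40), whose reads may be shared with HSPA6. PARN (3.17, SE 0.85) and SMN1 (3.03, SE 0.98) were measured with little precision. A candidate explanation is transcription that runs on from a rising gene upstream. Of the 44 genes with a known position, 3 (6.82%) had a gene upstream on the same strand that ended within 10 kb and rose at least 2-fold, against 1.28% of all placed genes (Fisher's exact test, 2-sided, p = 0.0185). These were PNLDC1, which begins 1.81 kb after MRPL18 (2.65), NECAB2, 2.30 kb after OSGIN1 (3.87), and LOC100128770, 4.73 kb after THOC6 (1.48). Most of the set thus had no rising same-strand gene ending within 10 kb upstream, and read-through of this kind stays possible for these 3 genes. Read-through from farther away, or from genes that did not rise, was not tested, and the libraries do not mark strand. The test therefore cannot settle read-through as a cause for the set.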
